A study of Synechococcus elongatus PCC 7942 = FACHB-805 with 16 samples.

How the data were processed

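Total RNA of 16 aliquots of Synechococcus elongatus PCC 7942 was labelled with 1 dye and hybridised to arrays of 15744 spots, 4 aliquots in each of 4 groups: control, Z-COTE, Z-COTE HP1 and ZnCl2. Groups and replicate numbers come from the labels. Per the labels' protocols, RNA was treated with DNase, amplified and labelled with Cy3, no spike-in RNA was added, and the cells came from 1 washed suspension. The amount of labelled RNA put on an array is not given in the sources used here. The files hold scanner exports with spot intensities on a linear scale, per the file headers, with the mean of each spot at 532 nm and the median of its local background, neither of them normalized. The deposited value table of the authors holds intensities for 2395 genes. R 3.3.0 and limma 2.16.5 are named in the submitters' processing notes, without saying what was done. Its columns have medians from 117 to 183 on a linear scale, correlate with the log2 scanner values at 0.962 or more across genes, and are lower in the exposed groups. How they were centred and whether background was removed stays unknown. They were used as an alternative.

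The design written before the data were examined assumed another scanner format, with its own corrected signal and detection call. The files gave spot means and local backgrounds, so the background was corrected with limma's normexp method (offset 50) on all spots, spots marked bad by the scanner software were left out, and values were taken to log2. A fold change on this scale understates the change of dim genes. A probe was called detected where its mean minus local background exceeded the median of 844 background spots on the same array (negative controls and spike-in probes, for which no RNA was added) by 3 SDs estimated from the median absolute deviation. A gene was detected where at least 1 of its 4 probes was. Net brightness is the mean minus local background minus the median of the background spots. At most 48.3% of the gene probes were detected on each of the 12 exposed arrays, so each array was scaled by the 75th percentile of the 2575 probes detected on all 16 arrays. That probe set was chosen after the detection rates were seen. The design had planned the 75th percentile of each array, and the percentile over all gene probes, the nearest to it, was kept as an alternative. Probes detected on fewer than 4 arrays were left out, and the mean of the remaining probes of a gene gave 2535 genes. Of the genes called and detected on all 8 arrays, 95.3% in both oxide comparisons and 95.6% after ZnCl2 had all probes on the same side of 0.

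A single limma fit (R 4.3.3, limma 3.58.1) of the 16 arrays with a mean per group gave the 6 comparisons, with moderated variances, Benjamini-Hochberg adjustment over genes and an adjusted p under 0.05 as the threshold. Measures of whole arrays were compared with exact two-sided permutation tests, adjusted over 66 tests. Values for which no scaling was used are called unscaled. They compare brightness as scanned at equal gain and include any difference in the amount of labelled RNA. A scaling moves all genes together, and the median scaled change over all 2535 genes was 1.27 after Z-COTE, 0.89 after Z-COTE HP1 and 1.14 after ZnCl2, against -0.05 for each of them with quantile normalization and -0.47, -0.43 and -0.46 in the authors' values. For a gene detected on all arrays of a group and on none of the other, a lower bound was computed from the brighter group's mean and, for each dim array, the higher of the gene's own value and the lowest detected probe. Saturated spots were kept.

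Simulated arrays had the real genes' means and spreads, with 200 of 2535 genes changed by 1 or 2 log2 units. The fit recovered 100% of both sizes for Z-COTE, 99% and 100% for Z-COTE HP1 and 97% and 100% for ZnCl2. False calls numbered 6, 15 and 16 in the same order. Differences between these rates were not tested and are not read as properties of the exposures. The real fits called 2335, 2265 and 2301 genes. Recovery when most genes are called was therefore not tested.

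Replicate numbers 1 and 2 of every group lie on slide 1 and numbers 3 and 4 on slide 2. Arrays of the controls differed more between slides (SD of the log2 difference 0.29 to 0.37) than within a slide (0.13 to 0.20). No pair of arrays held identical values, and correlations between replicates ran from 0.978 to 0.997.

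The 28 gene lists fixed beforehand were not tested, because the files name genes by numeric IDs and 0 of these occur in the reference table of gene names used here. The rule for named genes, written beforehand, took the 8 largest changes in each direction in each comparison with the controls and 5 between exposures, among called genes whose groups did not overlap. With IDs alone, the text gives only 2 in each direction: those with the largest mean scaled change over the 3 exposures among genes detected on all 16 arrays, never saturated, called and not overlapping in each exposure. This narrower choice was made after the values were seen. Alternatives covered background correction, scaling, the filter on dim probes, the summary of probes, the arrays in the fit, blocks for slide and replicate number, the variance model, array weights, the leaving out of each array and the authors' values.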

Results

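Gene expression was measured in the freshwater cyanobacterium Synechococcus elongatus PCC 7942 after exposure to zinc in 3 forms. Z-COTE is an uncoated zinc oxide nanomaterial and Z-COTE HP1 a coated one, both of the kind used as UV filters in sunscreens, and ZnCl2 supplied zinc in its ionic form. Cells from 1 suspension were divided into aliquots, left unexposed or given 5 mg/L of one of the materials for 5 h in very soft water under continuous light, and each of the 4 groups was represented by 4 one-colour arrays. Because the aliquots came from 1 suspension, the p-values measure the spread between aliquots and arrays only. The labels do not say whether 5 mg/L refers to the compound or to zinc. The arrays carried 4 probes for each of 2708 genes, which the files name by a numeric ID alone and do not pair with gene names or locus tags. The number of arrays limits the precision, and each slide of 8 arrays held 2 arrays of every group.

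The exposed cells gave far dimmer arrays than the unexposed cells. The 75th percentile of the net brightness of the gene probes, above the spots used as background, was 1623 ± 153 intensity units in the controls (SD, n = 4), against 81.1 ± 6.38 after Z-COTE, 127 ± 15.1 after Z-COTE HP1 and 93.3 ± 6.40 after ZnCl2 (SD, n = 4 each). The control value was therefore 20.0 times that after Z-COTE, 12.8 times that after Z-COTE HP1 and 17.4 times that after ZnCl2. The median gene probe lay under the detection limit of a single probe on all 12 exposed arrays, so for the median only a bound holds: the control value of 542 ± 37.9 units (SD, n = 4) was at least 11.0, 11.6 and 11.3 times as high. In the 75th percentile, all 4 arrays of each exposed group lay below all 4 control arrays (exact permutation test, two-sided, p = 0.0286 for each exposure, the smallest that 4 against 4 arrays can give, adjusted p = 0.046 over 66 tests of array measures). Its ratio was 21.9, 12.4 and 18.4 on slide 1 and 18.2, 13.2 and 16.4 on slide 2, in the same order. The background spots themselves had a median of 71.0 ± 4.55 units in the controls and 73.1 ± 0.629, 72.8 ± 3.86 and 71.8 ± 5.50 in the 3 exposed groups (SD, n = 4 each), and the scanner gain was 780 on every array.

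Fewer genes were detected after exposure. Of the 2708 genes, 2611 ± 12.1 were detected on a control array, against 1308 ± 100 after Z-COTE, 1633 ± 64.2 after Z-COTE HP1 and 1466 ± 152 after ZnCl2 (SD, n = 4 each, exact permutation p = 0.0286 for each exposure against the controls). With the background limit taken from the negative control spots alone, 2662 genes were detected on a control array. The exposed groups then had 1863, 1942.5 and 1734, in the same order (exact permutation p = 0.0286 for each). The brightest genes took a larger share of the measured signal after exposure. The 10 brightest genes of an array took 7.54% ± 0.477 of the net signal in the controls, 41.2% ± 1.64 after Z-COTE, 34% ± 2.25 after Z-COTE HP1 and 38.0% ± 1.15 after ZnCl2 (SD, n = 4 each). These shares are affected by saturation, since 25.8 ± 1.5 genes were saturated on a control array and between 7 and 8 on each exposed array. Saturation caps the brightness of the top genes, so the size of this difference is uncertain.

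**Figure D1:**
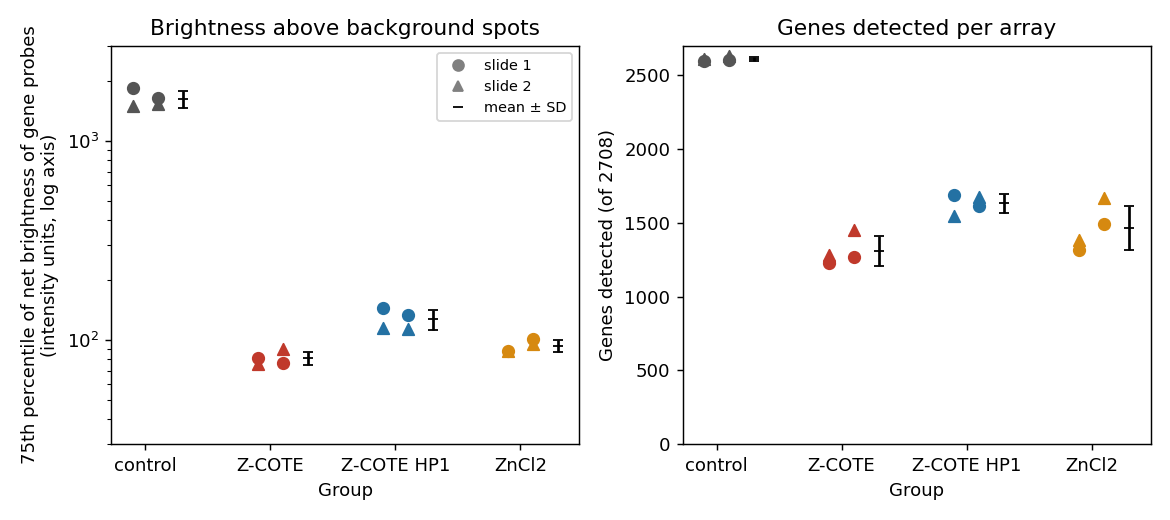
75th percentile of the net brightness of the gene probes in intensity units (left, log axis) and number of genes detected (right) on each of the 16 arrays, by group, with circles for slide 1, triangles for slide 2 and the mean ± SD beside each group. Every exposed array lies between 76 and 145 units, and every control array between 1495 and 1834 units.

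The comparison of Z-COTE with the controls asked how cells responded to the uncoated oxide. Of the genes detected on all 4 control arrays, 935 were detected on none of the 4 Z-COTE arrays, and no gene moved from undetected to detected on all arrays. Without scaling between arrays, those 935 genes were lower by at least 2.57-fold at the median of the lower bounds, and by at least 130-fold in the most extreme case, and 628 had a bound of 2-fold or more. After scaling on the genes still detected, 26 of them kept a bound above no change. A further 1038 genes were detected on all 8 arrays. Their unscaled change had a median of -2.82 on the log2 scale, and 90% of them lay between -5.22 and -0.41. Gene 637799546 was among the few that rose without any scaling, from a log2 brightness of 8.58 ± 0.32 in the controls to 11.36 ± 0.09 after Z-COTE (SD, n = 4). Gene 637800442 rose from 9.34 ± 0.24 to 11.28 ± 0.16. Genes 637800475 and 637800290 fell, with unscaled log2 changes of -6.99 and -6.84, from 14.63 ± 0.08 and 14.33 ± 0.11 to 7.63 ± 0.08 and 7.49 ± 0.11 (SD, n = 4). Relative to the 75th percentile of the probes detected on every array, the changes of the 4 genes were 6.32, 5.48, -3.45 and -3.29, with SEs of 0.11, 0.12, 0.10 and 0.10 (limma adjusted p of 3.6e-20, 5.8e-19, 1.5e-17 and 2.9e-17).

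Under that scaling, 2335 of 2535 genes were called changed by Z-COTE with limma (1628 by at least 2-fold), 1955 higher and 380 lower, but only 924 of them were detected on all 8 arrays, of which 653 were higher and 271 lower. Without scaling, 12 of 2535 genes were called higher and 2483 lower, so nearly all of the 1955 higher calls rest on the scaling. The scaling also lifts genes that lie at background or are saturated. Direction was read for the genes detected on all 8 arrays alone. It depends on the scaling: among the genes detected on all 8 arrays, the split was 496 higher and 339 lower with quantile normalization, 372 and 542 in the authors' processed values and 12 and 992 with no scaling. The 5 scalings compared were the main one, median centring, quantile normalization, the percentile over all gene probes and the authors' values. Under every one of these, 365 genes were called higher and 264 lower. With no scaling, only 12 of the 365 were also called higher, while all 264 were also called lower. The count was 2340 with slide as a block, 2307 within slide 1 and 2282 within slide 2. With the background taken from the control spots it was 2068, but the lower calls dropped to 118, and among detected genes the split was 636 higher and 106 lower.

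The comparison of Z-COTE HP1 with the controls asked the same of the coated oxide. Here 661 genes detected on all control arrays were detected on no exposed array, with an unscaled fall of at least 2.33-fold at the median of the bounds, and 417 of them had a bound of 2-fold or more. Under the main scaling, 27 of the 661 kept a bound above no change. The 1375 genes detected on all 8 arrays had a median unscaled change of -2.46 on the log2 scale. Gene 637799546 reached 11.36 ± 0.22 and gene 637800442 reached 12.10 ± 0.38, unscaled rises of 2.78 and 2.77, while the unscaled changes of genes 637800475 and 637800290 were -6.66 and -6.74 (SD, n = 4). Scaled, the changes were 5.79, 5.78, -3.65 and -3.73, with SEs of 0.11, 0.12, 0.10 and 0.10 (limma adjusted p between 7.0e-20 and 9.5e-18). The scaled fit called 2265 genes (1353 by at least 2-fold), 1790 higher and 475 lower, 1202 of them detected on all 8 arrays with 829 higher and 373 lower. That split was 600 and 433 with quantile normalization, 472 and 711 in the authors' values and 23 and 1311 unscaled. Over all genes, 23 were called higher and 2465 lower unscaled, so nearly all of the 1790 higher calls rest on the scaling. Under all 5 scalings 443 genes were called higher and 350 lower, of which 22 and 350 were also called so unscaled. The count was 2269 with slide as a block, 2199 within slide 1, 2202 within slide 2 and 1195 with the background taken from the control spots.

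The comparison of ZnCl2 with the controls gave the response to ionic zinc. In this group 751 genes went from detection on all control arrays to detection on none, by at least 2.52-fold unscaled at the median of the bounds, 507 of them with a bound of 2-fold or more and 24 with a bound above no change after scaling. The 1161 genes detected on all 8 arrays had a median unscaled change of -2.73. Genes 637799546 and 637800442 rose to 10.75 ± 0.27 and 11.62 ± 0.29, by 2.18 and 2.28, and genes 637800475 and 637800290 had unscaled log2 changes of -6.80 and -6.75 (SD, n = 4). Scaled, these changes were 5.57, 5.68, -3.40 and -3.35, with SEs of 0.11, 0.12, 0.10 and 0.10 (limma adjusted p between 2.3e-19 and 2.2e-17). The scaled fit called 2301 genes (1534 by at least 2-fold), 1893 higher and 408 lower, and 1020 of these were detected on all 8 arrays, with 711 higher and 309 lower. Of the calls among detected genes, 57.5% were higher with quantile normalization, where 393 were lower. The split was 404 and 604 in the authors' values and 22 and 1104 unscaled. Over all genes, 22 were called higher and 2473 lower unscaled, so nearly all of the 1893 higher calls rest on the scaling. Under all 5 scalings 397 genes were called higher and 297 lower, of which 22 and 297 were also called so unscaled. With slide as a block the count was 2309, within slide 1 it was 2248, within slide 2 it was 2249 and with the background taken from the control spots it was 1410.

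The genes that were brightest in unexposed cells lost signal in most cases. Of the 268 genes in the top 10% of control brightness that were never saturated, 216 fell by at least 8-fold unscaled after Z-COTE, 179 after Z-COTE HP1 and 211 after ZnCl2. Most of them stayed detectable, with 250, 260 and 258 detected on all 4 exposed arrays. Their median unscaled changes were -4.39, -3.94 and -4.18 on the log2 scale, with SDs between genes of 1.62, 1.66 and 1.66. In the same order, 8, 10 and 12 of them had a mean above that of the controls. Genes that are dim in the controls lie close to background and cannot show an 8-fold fall. Such falls are therefore not read as a trait of the brightest genes.

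A set of 48 genes fell less than the rest. The numeric IDs form a series of 2660 genes and, after a wide gap in the numbers, a second series of 48 genes. The files do not say what separates them. All 48 were detected on all 16 arrays, against 35.5% of the first series. Their median unscaled change was -0.50 after Z-COTE, -0.20 after Z-COTE HP1 and -0.01 after ZnCl2 (SD between genes 1.09, 1.01 and 1.12), when the genes of the first series detected on all 8 arrays had medians of -2.88, -2.53 and -2.80. The difference between the series was 2.39, 2.32 and 2.78 on the log2 scale. On slide 1 it was 1.97, 2.14 and 2.76, and on slide 2 it was 2.74, 2.46 and 2.77. Single exposed arrays ranged from 2.00 to 2.86. Without scaling limma called 3, 7 and 12 of the 48 genes higher and 25, 20 and 19 lower, so the members did not move as one. Relative to the probes detected on every array, 46, 46 and 47 of the 48 were called higher and 1 was called lower in each exposure. Under that scaling most genes detected on all 8 arrays were called higher as well: 653 of 1038, 829 of 1375 and 711 of 1161. A factor per array leaves the difference between the series as it is. Of the scalings that could change it, the authors' values gave 1.95, 1.49 and 2.31, and quantile normalization gave 2.27, 2.11 and 2.69.

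**Figure D2:**
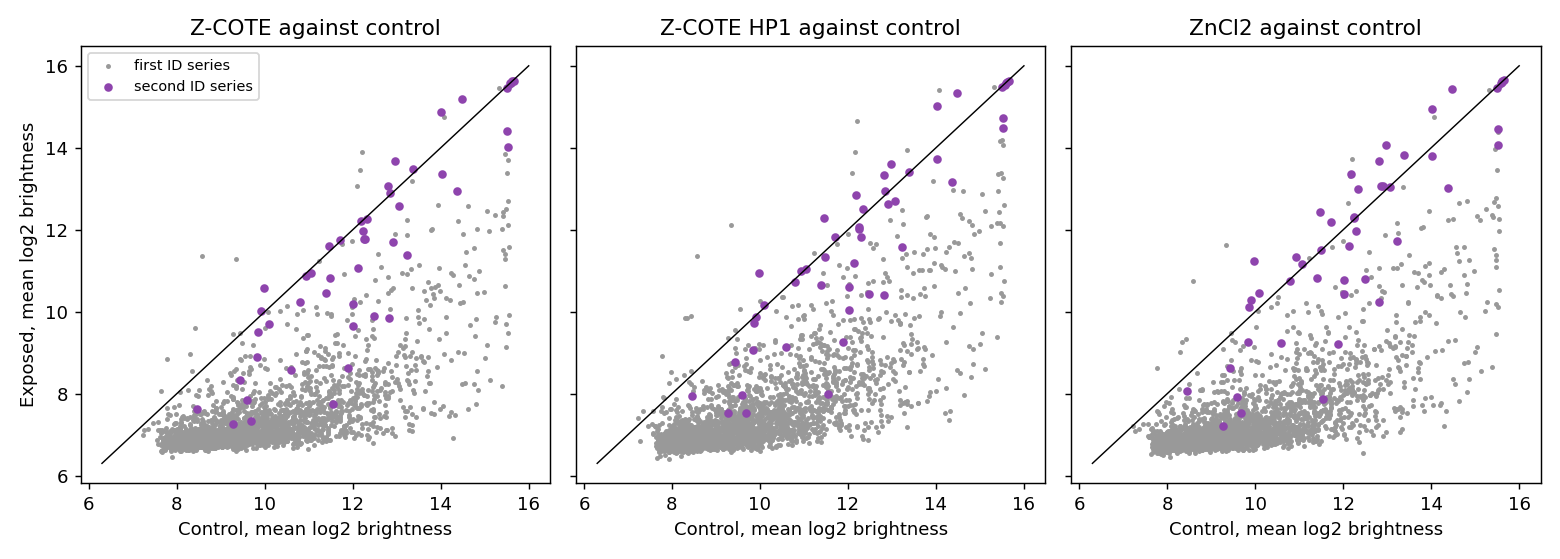
Mean log2 brightness of each of 2535 genes, without scaling between arrays, on the 4 arrays of each exposure (vertical) against the 4 control arrays (horizontal), with the 48 genes of the second ID series in purple, the first series in grey and a line at equal brightness. Most grey points lie well below the line and many flatten at background, while the purple points have median changes of -0.50, -0.20 and -0.01.

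Under the main scaling, the 3 exposures changed largely the same genes in the same direction. Over the 1030 genes detected in the controls and in both oxide groups, the scaled log2 changes after Z-COTE and Z-COTE HP1 had a correlation across genes of 0.978, and the values were 0.992 for Z-COTE and ZnCl2 over 993 genes and 0.983 for Z-COTE HP1 and ZnCl2 over 1134 genes. Genes are not independent replicates, and the exposures share their control arrays. Unchanged groups simulated against shared controls gave 0.496, 0.497 and 0.494. The covariances were 2.03, 2.16 and 1.95, against simulated covariances of 0.0078, 0.0078 and 0.0076. The simulated groups held no loss of brightness. They cannot separate a shared loss that grows with control brightness from responses of single genes. With the controls divided so that each exposure had 2 arrays of its own, the lowest correlations were 0.935, 0.958 and 0.958. In the first pair 599 genes were called higher in both and 244 lower in both, where independent lists would share 387 and 77.1, and 6 genes were called in opposite directions. In the second pair the shared counts were 587 and 256 against 367 and 75.9, with 0 opposite calls. In the third they were 649 and 281 against 411 and 87.4, with 3 opposite calls. Independent lists take no account of the shared controls or of a shared loss of brightness. The excess over them cannot separate these from responses of single genes. Of the 991 genes detected on all 16 arrays, 558 were called higher and 236 lower in all 3 exposures under the main scaling. By at least 2-fold these were 341 and 102. Without scaling, only 12, 23 and 22 detected genes were called higher after Z-COTE, Z-COTE HP1 and ZnCl2. The lower calls were then 992, 1311 and 1104.

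The coated and the uncoated oxide were compared directly to ask what the coating changed. The 75th percentile of net brightness was 127 units after Z-COTE HP1 against 81.1 after Z-COTE (exact permutation p = 0.0286, adjusted p = 0.046). The median unscaled log2 brightness of the second ID series did not pass the test (11.69 against 11.37, exact permutation p = 0.171, with differences of 0.71 on slide 1 and -0.08 on slide 2). Medians over all gene probes or over the first series were not set against Z-COTE, since they lay under the detection limit or, for the first series, had under 50% of the genes detected on 3 of the 4 Z-COTE arrays. Z-COTE HP1 arrays had 325 more detected genes (1633 against 1308, exact permutation p = 0.0286, adjusted p = 0.046), with 406 more on slide 1 and 245 more on slide 2, and 51 genes were detected on all 4 Z-COTE HP1 arrays and on no Z-COTE array. With the background limit taken from the negative control spots alone, the difference was 79.8 genes and did not pass the test (exact permutation p = 0.714). Without scaling, limma called 547 genes brighter after Z-COTE HP1 and 0 dimmer (756 and 12 at an unadjusted p under 0.05). Of the 547, 53 were brighter by at least 2-fold. Relative to the detected probes, the 1031 genes detected on all 8 arrays differed little in size, with the largest difference at 0.96 on the log2 scale and 887 of them within 0.5. The median 95% half-width of an estimate was 0.22, and for 1009 of the 1031 the interval lay within 2-fold of no difference. The scaled fit called 1990 genes in all (2 by at least 2-fold), 106 higher and 1884 lower after Z-COTE HP1, of which 598 were detected on all 8 arrays with 103 higher and 495 lower. Among detected genes that split turned to 212 and 120 with the percentile over all gene probes, the scaling nearest to the design, to 135 and 83 with quantile normalization and to 142 and 73 in the authors' values, with 282 and 257 genes called in all. Under all 5 scalings 82 genes were higher, with a median difference of 0.48, and 39 were lower, with a median of -0.56. Without scaling, all 82 were also called higher and 0 of the 39 lower. The count was 2020 with slide as a block, 1974 within slide 1 and 1280 within slide 2. With the background taken from the control spots it was 2128, and among detected genes 17 were higher and 621 lower.

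Between Z-COTE and ZnCl2, the 75th percentile of net brightness, 81.1 against 93.3 units, did not pass the test (exact permutation p = 0.0857), nor did the net signal summed over never saturated genes, 1.17 times as high after ZnCl2 (exact permutation p = 0.0571). The median log2 brightness of the second ID series was lower after Z-COTE, 11.37 against 11.87 (exact permutation p = 0.0286, adjusted p = 0.046), with differences of -0.89 on slide 1 and -0.10 on slide 2. Relative to the detected probes, over 994 genes detected on all 8 arrays, 971 differed by less than 0.5 on the log2 scale, and for 982 the 95% interval lay within 2-fold of no difference. Limma called 22 genes, 10 higher and 12 lower after Z-COTE, none by 2-fold and 20 of them detected on all 8 arrays. Without scaling the split was 0 higher and 17 lower (32 and 169 at an unadjusted p under 0.05), 2 of them lower by at least 2-fold. The second ID series had a median scaled difference of -0.22, lower after Z-COTE (SD between genes 0.31), and 1 of the 48 genes passed the test. With quantile normalization 54 genes were called, 27 in each direction, and in the authors' values 35, 13 higher and 22 lower. Under all 5 scalings 5 genes were called higher and 8 lower, but 0 of the 5 were called higher without scaling. The count depends on the setting, with 2064 genes when the background is taken from the control spots (2054 higher and 10 lower), 276 with array weights, 87 with only the 8 arrays in the fit, 31 when slide is a block, 8 within slide 1, 6 within slide 2, and between 7 and 33 when 1 array is left out. The number of detected genes, 1308 against 1466, did not pass the test (exact permutation p = 0.143).

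Z-COTE HP1 and ZnCl2 arrays differed in some measures of brightness and not in others, and genes were called between them in numbers that depend on the setting. The share of net signal taken by the 10 brightest genes was lower after Z-COTE HP1 (exact permutation p = 0.0286, adjusted p = 0.046), though saturation affects it. The 75th percentile of net brightness was 127 against 93.3 units (exact permutation p = 0.0286, adjusted p = 0.046), by 45.0 units on slide 1 and 22.5 on slide 2. The median log2 brightness of the first ID series did not pass the test (7.11 against 7.02, exact permutation p = 0.114), with over 50% of these genes detected on all 4 Z-COTE HP1 arrays and on 3 of the 4 ZnCl2 arrays. Among the 1135 genes detected on all 8 arrays, limma called 442, with 99 higher and 343 lower after Z-COTE HP1, out of 1393 calls in all (99 higher and 1294 lower, 1 by at least 2-fold). The largest difference was 1.18 on the log2 scale, and for 1107 genes the 95% interval lay within 2-fold. Genes of the second ID series had a median scaled difference of -0.52 (SD between genes 0.22), and 38 of the 48 were called lower and 0 higher, where 1294 of all 2535 genes were called lower. Without scaling their median was -0.14, with 2 called lower and 1 higher, and their median log2 brightness per array, 11.69 against 11.87, did not pass the test (exact permutation p = 0.4). The split among detected genes turned to 155 higher and 92 lower with the percentile over all gene probes, and was 107 and 73 with quantile normalization and 98 and 83 in the authors' values, where 204 and 191 genes were called in all, against 366 and 12 with no scaling. Under all 5 scalings 63 genes were higher and 52 lower, 19 of the 52 being members of the second series. Without scaling, all 63 were also called higher and 11 of the 52 lower. The count was 1443 with slide as a block, 1125 within slide 1 and 312 within slide 2, and 794 without Z-COTE HP1 replicate 1. With the background taken from the control spots limma called 0 genes (45 at an unadjusted p under 0.05), against 2064 for Z-COTE and ZnCl2, so the order of these counts depends on the background correction. The number of detected genes, 1633 against 1466, did not pass the test (exact permutation p = 0.0857).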

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

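The tests of slide and of an equal loss for every gene, for lower signal, and those of saturation and of carried-over DNA, for the second ID series, were chosen after values that bear on them were seen.

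In 5 of 52 groups of 4 values, 1 value stood far from the rest, where chance gives about 1 in 20. Z-COTE replicate 4 had 8 saturated genes against 7 on the other arrays of its group, and Z-COTE HP1 replicate 3 and ZnCl2 replicate 3 had 7 against 8, so these 3 cases rest on a single gene. In ZnCl2 replicate 3 the 10 brightest genes took 39.8% of the net signal, against 37.4% to 37.5% on the other 3 arrays. Control replicate 1 had a log2 brightness of 9.70 for gene 637800442, against 9.20 to 9.24 in the other controls and a lowest exposed group mean of 11.28.

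Spots that carry chromosome sequence without a gene ID, in 2 sets by their names, were left out of the fits of genes. In 1 set, limma called 1 of 1847 spots brighter than the controls without scaling after Z-COTE, 3 after Z-COTE HP1 and 1 after ZnCl2, with the largest rise at 0.55 on the log2 scale, while 1666, 1667 and 1682 were dimmer. In the other set, of 1858 spots, 1747, 1746 and 1763 were dimmer.

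All 12 exposed arrays had lower gene signal than all 4 controls. A difference between slides or scans is argued against, since the smallest fold in the 75th percentile of net brightness was 12.4 within slide 1 and 13.2 within slide 2, at equal gain. The same loss of labelled RNA for every gene is argued against as the whole cause, since between 12 and 23 genes were called brighter without scaling. A few genes taking most of the labelled RNA cannot be told apart from a general loss: the summed net signal of never saturated genes was at least 6.99 times lower and at most 9.94 times lower, but the limit set beforehand on that sum was wrong, because genes taking the label would lower that sum too and the brightest genes are saturated. A lower content of messenger RNA in exposed cells, and a smaller amount of usable RNA or label in those samples, stay open and were not tested.

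The second ID series of 48 genes lost less brightness than the first. Saturation is argued against, since the 40 members that were never saturated had medians from -0.61 to -0.03 on the unscaled log2 scale. Carried-over DNA at 1 level in every sample is argued against as their whole signal. Between 24 and 28 of those 40 were called changed, in both directions. Higher control brightness is argued against, since the members exceeded the 10 first-series genes nearest in control brightness by a median of at least 2.60 and at most 3.22. As a hypothesis, transcripts of these genes may be made or kept differently under zinc exposure, but what the series is stays unknown here. DNA carried over despite the DNase treatment, in varying amounts or at 1 level beneath a changing RNA signal, was not tested.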

How the results depend on the processing

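No scaling, the main probe set for scaling, the percentile over all gene probes and the control-spot background were chosen after seeing the data. So were plain subtraction, the detected-gene count, the slide subsets, leaving out the second ID series and the other background limits. Low signal over background on the exposed arrays limits which genes can be compared in direction. The changes of the 4 named genes kept their direction and passed the test in each exposure under all 25 alternatives run for them. These genes were picked for large changes in the same data, so this says little about other genes. Counts are of genes called. The numbers do not pair the samples: same-numbered arrays had correlations of deviations from -0.11 to 0.30, 5 of 24 over 0.1, and 8 of 16 arrays correlated best with their own number. With the replicate number as a block the counts were 2335, 2265, 2309, 2009, 27 and 1399 for Z-COTE, Z-COTE HP1 and ZnCl2 against control, Z-COTE HP1 against Z-COTE, Z-COTE against ZnCl2 and Z-COTE HP1 against ZnCl2, so no count moved by over 1.5 times. In each comparison, the real division of the 8 arrays was the 1 of 35 with as many genes called, the smallest share possible: the real counts were 2335, 2265, 2301, 1990, 22 and 1393 and the highest others 0, 0, 0, 837, 0 and 405 (limma; at an unadjusted p under 0.05, real counts of 2338, 2272, 2308, 2029, 524 and 1610 and highest others of 1484, 1349, 1450, 1417, 526 and 1142). For the 3 comparisons with controls, chance can be excluded only at that share. Other divisions put exposed and control arrays in 1 group, which widens its spread, so their counts of 0 add little. Chance is left open for Z-COTE against ZnCl2, where another division gave as many genes unadjusted. It is also open for pairs with Z-COTE HP1: most genes called were not detected on all 8 arrays and move with the scaling. Leaving out 1 array gave 1794 to 2320, 1728 to 2253, 1775 to 2290, 1841 to 2004, 7 to 33 and 794 to 1590, in that order.

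For the first 3 comparisons, probes above background on all 16 arrays gave 761, 760 and 760, since 858 genes are then tested, and counting only genes detected on all 8 arrays gave 924, 1202 and 1020. The control-spot background gave 1195 for Z-COTE HP1 and 1410 for ZnCl2, and 2068 for Z-COTE with 118 lower. For Z-COTE HP1 against Z-COTE the counts were 282 (quantile), 257 (authors' values), 414 (probes on all 16), 598 (detected genes), 547 (no scaling), 1157 (percentile over all gene probes), 1214 (plain subtraction) and 1280 (slide 2 alone). For Z-COTE HP1 against ZnCl2 they were 204 (quantile), 885 (median centring), 191 (authors' values), 263 (probes on all 16), 442 (detected genes), 409 (no scaling), 471 (percentile over all gene probes), 500 (plain subtraction), 312 (slide 2 alone), 794 without Z-COTE HP1 replicate 1, and 0 with the control-spot background (limma; 45 at an unadjusted p under 0.05). For Z-COTE against ZnCl2 they were 54 (quantile), 35 (authors' values), 60 (probes on all 16), 87 (only the 8 arrays), 276 (array weights), 2064 (control-spot background), 8 and 6 (slides 1 and 2 alone), and, without 1 array, 8, 7, 13 and 13 for Z-COTE replicates 1 to 4 and 7 and 13 for ZnCl2 replicates 3 and 4. With background limits from negative control spots alone, Z-COTE HP1 arrays had 79.8 more detected genes than Z-COTE arrays (exact p = 0.714), and Z-COTE arrays 129 more than ZnCl2 arrays, a reversed difference (main value -158, neither past the test). Apart from the cases explained above, the cause was not tested. Normexp, planned as an alternative, became the main setting. The percentile of each array, planned as the main scaling, was not used. The percentile over all gene probes, the nearest to it, was added as an alternative after the data were seen. The gene list alternatives were not run because no gene could be named.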

Other observations

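The pattern below was noticed first, and both of its tests were chosen before their results were seen. Genes whose IDs differ by 1 tended to change alike. Over 444 such pairs of first-series genes that were detected on all 16 arrays and never saturated, the mean unscaled changes had a correlation across genes of 0.314, above the highest of 1000 shuffles, 0.141. After removing the trend with control brightness the correlation was 0.304, against a highest shuffled value of 0.137, so similar brightness of neighbours does not account for it. The files do not say what the order of the IDs follows. As a hypothesis, neighbouring IDs may belong to genes transcribed together, which the data here cannot show.

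The authors' value table leaves out 313 of the 2708 genes on the array, 9 of them detected on all 16 arrays.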
